A study of Mus musculus with 4 samples.

How the data were processed

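RNA of mouse platelets was sequenced in 4 libraries, 1 per group: WT mice and littermates labelled as HuR conditional knockouts (cKO) at 3 months of age, and Young (3 months) and Old (24 months) wild-type mice, all male. Per the series' design text, the platelets of 7 mice were pooled for each library. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and genome build mm10 were used. The notes give no role or order for these tools, and neither the counting of reads shared by several genes nor the use of strand is given in the sources used here. The labels state a minimum RNA integrity for library making and no sort or gate of the platelets.

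The authors deposited 2 tables, 1 for cKO and WT and 1 for Old and Young, each with a signal per gene and library, which the values show to be reads scaled to a common library size within that table. Each value is a whole number of reads times 1 step per library, plus a small constant. Dividing by the step gave whole reads within a tolerance of 0.02 read for at least 99.92% of values in every library. The ratio of the steps was 0.98244 for cKO over WT and 1.095 for Old over Young, the inverse of the ratio of trimmed-mean (TMM) library sizes of the recovered reads. The design, fixed before the data were examined together with the gene lists, the naming rule and most of the alternatives, assumed counts. The deposited values are scaled, so the recovered reads were used in their place. Genes with fewer than 2 reads over both libraries of a table are not listed in it, which leaves 16467 genes in the first table and 16180 in the second. The authors' deposited table also gives a log2 fold change and, per the file headers, a p-value and an adjusted p-value for each comparison. The test behind the deposited p-values is not given in the sources used here, and each compares 2 libraries, not the conditions. A further 4 per-sample columns have names that match no sample and were not used.

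No test across replicates is possible with 1 library per group, and no count test was run. Library sizes were scaled by TMM (edgeR 4.0.16 in R 4.3.3), separately for each pair compared. Because the authors scaled the 2 tables separately, comparisons across them were made on the recovered reads of the genes in both tables. For each gene the ratio of reads over the scaled library sizes is given with an exact 95% interval from the Clopper-Pearson interval of the share of its reads that fell in 1 of the 2 libraries. The interval covers counting error only, since amplified reads without molecular identifiers are not independent molecules, and it leaves out the spread between pools of mice. A gene passed the size rule when the larger count was at least 100 reads and the interval bound nearest to 1 was at least 2-fold. For a gene with 0 reads in 1 library the fold is computed against a floor of 3 reads and leaves out the counting error of the other library, so that the interval bound is lower. The floor is a level of 0.167 RPM (reads scaled to the library total) in WT, 0.169 in cKO, 0.165 in Young and 0.162 in Old. Shares of reads per library rest on at least 17702341 reads. Their Wilson intervals are narrow, for example 0.782% to 0.790% for haemoglobin genes in WT and 0.0136% to 0.0147% for immunoglobulin genes in Old.

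The 27 gene lists cover platelet and megakaryocyte genes, pathways, reported HuR targets and markers of the other cells a platelet preparation can hold. A list's value is the median log2 ratio of members with at least 20 reads over both libraries, with a pseudocount of 0.5 read. It is set among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and is said to stand apart outside their central 95%. The percentile describes these libraries and is no p-value. The mean had the other sign from the median for the immediate-early list (0.03 and -0.08) and the structural RNAs (-0.12 and 0.29) in cKO over WT, for cell cycle genes (-0.09 and 0.08) in Old over Young, and for senescence (-0.08 and 0.02) and MHC class I genes (0.01 and -0.06) in WT over Young. WT over Young served as a yardstick: a gene lies outside it when its ratio is beyond the central 95% of WT over Young ratios in the same of 20 expression bins. The yardstick shares WT with cKO over WT and Young with Old over Young, so it is independent of neither.

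Genes were named by a rule: Elavl1; per comparison the 10 highest and 10 lowest protein-coding genes past the size rule, ranked by the interval bound nearest to 1 and without clone names; up to 4 members per list with the largest ratio among those with at least 100 reads; the 10 most abundant genes of each library; and up to 6 genes shared by both comparisons in the same and in opposite directions. Genes named outside it were chosen after their values were seen: further list members past the size rule, Thbs1 and Rgs18 outside cKO over WT, the copies Tpm3-rs7 and Rps3a2, and genes named in the closing section. Coordinates are those of the deposited tables (mm10).

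The recovery of reads and the size rule were tested on simulated data with known folds. In cKO over WT (the library labelled cKO against WT, 16467 genes) the rule took 95.5% of genes changed 3-fold and 100% of those changed 4-fold or 8-fold. In Old over Young (16180 genes) it took 92.5% of those changed 3-fold and 100% at 4-fold and 8-fold, and in WT over Young (14438 genes) 100% at each. It called 0 unchanged genes, and the intervals held the true ratio for 95.3%, 94.9% and 95.5% of genes. Of 100 random lists, drawn from all simulated genes with the changed ones left in, 4, 5 and 8 stood apart. The simulations hold counting error only. Alternatives covered the scaling (median of ratios in DESeq2 1.42.0, plain totals, and totals without mitochondrial and haemoglobin genes), the minimum of reads, the fold bound, protein-coding genes only, thinning to the smallest library, the pseudocount, the mean of members, the authors' fold changes and the pairing of libraries. Using the other 3-month wild-type library as reference was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.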

Results

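RNA of mouse platelets, the small anucleate blood cells that form clots, was sequenced in 4 libraries. A conditional knockout of HuR (an RNA-binding protein that binds AU-rich elements in messenger RNAs and is encoded by Elavl1) in platelets was set against wild-type littermates at 3 months of age, giving the libraries labelled cKO and WT. Platelets of Young (3 months) and Old (24 months) wild-type mice gave the other pair. All mice were male, and each library held the pooled platelets of 7 mice. The recovered read totals were 17978384 for WT, 17702341 for the library labelled cKO, 18145612 for Young and 18472149 for Old. With 1 library per group there is no replicate check on any difference, and every interval given covers counting error only. A gene is said to have risen or fallen when its larger count was at least 100 reads and the bound of its 95% interval nearest to 1 was at least 2-fold.

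Elavl1, the gene targeted in the knockout, was not lower in the library labelled cKO. The gene (ENSMUSG00000040028, protein coding, mm10 chromosome 8, 4285382 to 4325413, minus strand) had 876 reads in WT, 1481 in the library labelled cKO, 621 in Young and 527 in Old. The ratio of the library labelled cKO to WT was 1.66 (1.53 to 1.81), and against Young it was 2.62 (2.38 to 2.88). The deposited values thus show no loss of Elavl1 reads and do not bear out the genotype label. Every direction given for this library below is a direction for the library labelled cKO, not for loss of HuR. The counts are per gene and cannot show whether an exon was deleted. Elavl1 was 0.929 times the Young level in Old (0.826 to 1.05), a difference not detectable at this depth, but 0.603 times the WT level (0.540 to 0.672). It was 1.54 times the Young level in WT (1.39 to 1.71). In the authors' deposited table the Elavl1 log2 fold change of the library labelled cKO over WT was 0.73, with p = 0.0797 and adjusted p = 0.371.

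Tmsb4x, encoding the actin-binding peptide thymosin beta, was the most abundant gene in all 4 libraries, with 6.86% of reads in WT, 4.65% in the library labelled cKO, 6.15% in Young and 4.57% in Old. Fth1, B2m, Ppbp, Tsc22d1, Ctla2a, Cd9 and Nrgn were among the top 10 of every library, and the top 10 together took 23%, 20.9%, 21.4% and 17.6% in the same order. Itga2b (the platelet integrin alpha chain) joined the top 10 in the library labelled cKO, Young and Old, Plek in WT and Old, Gng11 in WT, and Hba-a1 in the library labelled cKO and Young. Haemoglobin genes held 0.786% of reads in WT, 1.44% in the library labelled cKO, 2.02% in Young and 1.04% in Old. Mitochondrially encoded genes held 2.33%, 2.02%, 1.76% and 2.27%, cytosolic ribosomal protein genes 1.16%, 1.13%, 1.24% and 0.774%, immunoglobulin genes 0.0508%, 0.0366%, 0.0369% and 0.0141%, and the platelet receptor and granule list 14.5%, 13.5%, 13.9% and 15.4%.

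**Figure D1:**
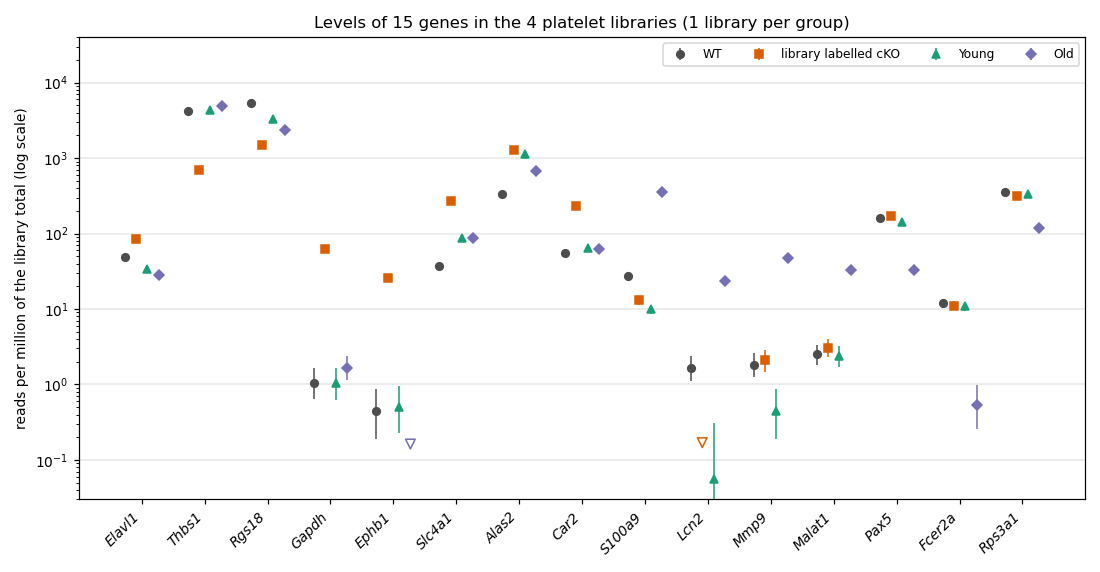
Reads scaled to the library total (RPM, log axis) for 15 genes in WT, the library labelled cKO, Young and Old, 1 library each, with exact 95% counting intervals where these exceed the symbols; open triangles mark the 3-read floor of a library with 0 reads. Thbs1 was at 686 RPM in the library labelled cKO against 4157 in WT, S100a9 at 355 in Old against 9.86 in Young, and Car2 and Alas2 were chosen for the plot after their values had been seen.

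The library labelled cKO was compared with WT, its littermate library. Erythroid markers were higher in the library labelled cKO, and single platelet genes, Thbs1 and Rgs18 among them, were lower. Slc4a1, the red-cell anion exchanger (chromosome 11, 102348824 to 102366203), rose 7.14-fold (6.58 to 7.76; 4820 against 663 reads), and Ank1, the red-cell ankyrin, rose 7.62-fold (5.49 to 10.8). Thbs1 (thrombospondin, an adhesive glycoprotein of alpha granules; chromosome 2, 118111876 to 118127133) was 6.26-fold lower (6.14 to 6.38; 12152 against 74741 reads), and Rgs18, a platelet regulator of G-protein signalling (chromosome 1, 144752683 to 144775435), was 3.70-fold lower (3.65 to 3.75; 26767 against 97351 reads). Of 6273 genes with at least 100 reads in the larger library, 158 rose and 107 fell, and 20 and 7 of them passed at a bound of 4-fold.

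Outside the erythroid marker list, the largest increases were in Gapdh, at 57.9-fold (36.9 to 96.5; 1119 against 19 reads), and Ephb1, an ephrin receptor kinase, at 55.4-fold (27.9 to 129; 451 against 8 reads). Gapdh has many near-identical copies in the genome, so its count depends on how shared reads were assigned and is uncertain. Tspan33 rose 6.90-fold, Apol11b 5.67-fold, Cnn1 (calponin, a smooth-muscle actin-binding protein) 5.65-fold, Col18a1 (a basement-membrane collagen) 7.59-fold and Fam220a 5.12-fold. Fam220a, too, can share reads with copies. Among the genes that fell, Slc18a2, the vesicular monoamine transporter that loads serotonin into dense granules, was 4.11-fold lower (3.53 to 4.81). Pfkfb3, a regulator of glycolysis, was 3.76-fold lower, Cd274, an immune checkpoint ligand, 3.94-fold, Pld2, a phospholipase, 3.92-fold, and Mllt3, a chromatin reader, 3.70-fold. Ociad2 was 6.29-fold lower, Serpini1 4.92-fold and Lamp5 17.8-fold (7.92 to 49.6; 6 against 105 reads).

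Of the 38 measured platelet receptor and granule genes, 0 rose, 3 fell and 35 did neither. Thbs1, Rgs18 and F2rl2 (a thrombin-related receptor, 2.33-fold lower) were those that fell, and Selp (P-selectin) had a ratio of 0.486 without passing. The list median was -0.16 on the log2 scale, at percentile 5.19 of 10000 random lists matched on expression. Of 40 integrin and actin cytoskeleton genes, Actg1 rose 2.23-fold and Itga2, the collagen-receptor integrin chain, fell 2.39-fold, with a median of 0.02. Of 16 secreted cytokine and growth factor genes 1 fell, Angpt1 (2.77-fold lower), and the median of -0.34 lay at percentile 1.44, while Pdgfa had a ratio of 2.00 and Il1b 0.398. The median of the 27 measured mRNAs reported as HuR targets lay inside the random range (-0.06, percentile 32.2). Thbs1 fell, Cdkn1a (a cell cycle inhibitor) rose 4.91-fold (3.30 to 7.53) and 25 did neither. The summed reads of the list had a ratio of 0.697, with Thbs1 holding 74741 of 140459 reads in WT and 12152 of 99714 in the library labelled cKO. The AU-rich element binding proteins, Elavl1 among them, included Pcbp1 at 2.16, Hnrnpab at 2.03 and Celf2 at 0.508, and 0 of 17 passed (median 0.24, percentile 96.1).

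Of 40 interferon-stimulated genes, Rsad2 and Isg15 rose 3.71-fold and 3.27-fold, yet the list median was lower, at -0.29 (percentile 0.32; the summed reads had a ratio of 1.11), with Rtp4 at 0.521 and Trim30a at 0.564. Proteasome subunits had a median of -0.31 (percentile 0.1) with 0 of 31 passing, and Psmb2 at 0.406. The nuclear oxidative phosphorylation median was -0.17 (percentile 0.8; 1 of 73 fell, Atp5e, 2.36-fold), and the ribosomal protein median -0.14 (percentile 1.65; 0 of 78 passed, Rplp1 at 2.03). Ube2c (3.98-fold) and Nusap1 (2.71-fold), genes of dividing cells, rose among 21 cell cycle genes, whose median was 0.04. Medians inside the random range were 0.14 for 16 megakaryocyte transcription factors, 0.23 for 20 senescence genes (Cdkn1a rose), -0.04 for 16 MHC class I genes (summed reads had a ratio of 0.694), -0.21 for 12 mitochondrially encoded mRNAs, 0.24 for 18 glycolysis genes (Gapdh rose), 0.03 for 22 immediate-early and heat shock genes, -0.12 for 6 nuclear retained and structural RNAs (Neat1 rose 2.75-fold) and -0.42 for 4 Y-linked genes.

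Markers of other blood cells moved with these groups. Of 29 erythroid markers 15 rose, 1 fell and 13 did neither, with a median of 1.52 (percentile 100). Ank1 and Slc4a1 were joined by Tspo2 (6.26-fold) and Trim10 (5.41-fold). The 1 that fell was Hba-a2, 2.29-fold, while Hba-a1 had a ratio of 1.93. These 2 genes are near-identical copies, and their summed reads had a ratio of 1.66 (1.65 to 1.67). Neutrophil markers had a median of -0.85 (percentile 0.02; 0 of 16 passed; S100a8 0.435, S100a9 0.466), the same with its 2 members at 0 reads in 1 library set at their bound. Monocyte and macrophage markers had a median of -0.42 (percentile 1.79; 0 of 20 passed; Ms4a6b 0.465), B cell markers -0.25 (percentile 2.31; 0 of 22 passed; Fcrla 0.615) and immunoglobulin and plasma cell genes -0.39 (percentile 2.27; 0 of 15 passed; Iglc2 0.463). Medians of -0.16 for T and NK cell markers (Gzma fell 3.03-fold), -0.05 for MHC class II and dendritic cell markers (Xcr1 fell 2.42-fold), -0.30 for basophil and mast cell markers and 0.16 for endothelial markers lay inside the random range.

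Against Young, the other wild-type library of the same age, a comparison chosen after seeing the data, the library labelled cKO had 133 genes higher and 51 lower. Of the 158 and 107 genes past the rule against WT, 73 and 28 also passed against Young in the same direction, and 0 passed in the opposite one. Thbs1 (5.97-fold lower), Slc18a2 (3.74-fold lower), Pfkfb3 (3.18-fold lower), Itga2 (2.25-fold lower), Gapdh, Ephb1, Cnn1, Ank1 and Slc4a1 (3.37-fold higher) were among them. Rgs18 (2.01-fold lower, 1.98 to 2.04), F2rl2, Angpt1 and Cd274 were not, and Isg15 had a ratio of 1.05. The comparisons with WT and with Young share the library labelled cKO, so agreement between them is partly built in. Passing in opposite directions would need WT and Young to lie about 4-fold apart or more. At a bound of 4-fold, 0 genes were higher and 4 lower in WT than in Young. The 0 reversals thus add little support. The erythroid median against Young was 0.55. Of the other lists that stood apart against WT, proteasome (-0.27, percentile 0.13), oxidative phosphorylation (-0.16, percentile 0.29) and ribosomal protein genes (-0.15, percentile 0) stood apart downward again, the medians of secreted factors (0.11), neutrophil (0.21), B cell (0.17) and plasma cell genes (0.06) changed sign and lay inside the random range, and the interferon median was -0.08 and inside it too. Monocyte and macrophage markers stood apart in opposite directions, downward against WT and upward against Young (0.67, percentile 99.8). Platelet genes (-0.06, percentile 0.93) and T and NK cell markers (-0.73) stood apart downward against Young though not against WT, and immediate-early and heat shock genes (0.32) and endothelial markers (0.57) upward. In the authors' deposited table, adjusted p was under 0.05 for 624 genes (337 higher, 287 lower), among them 204 of the 265 genes past the rule. The test behind those p-values is not given in the sources used here.

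**Figure D2:**
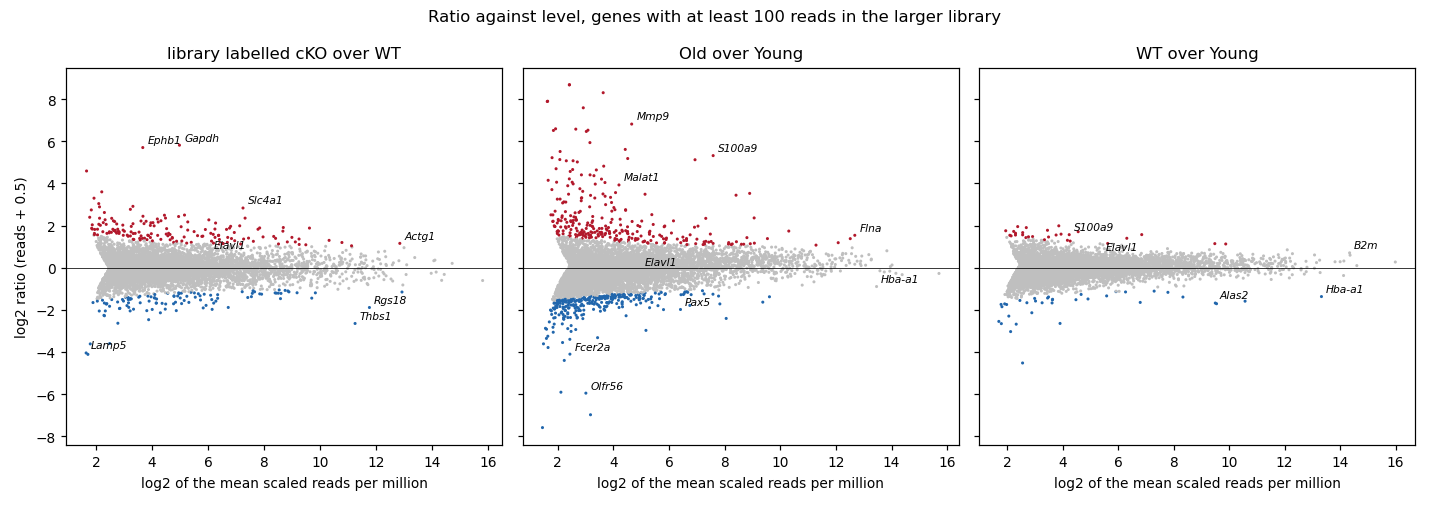
Log2 ratio of each gene (y axis) against the log2 of its mean scaled RPM (x axis) for genes with at least 100 reads in the larger library, in 3 comparisons of single libraries; red and blue points are genes that rose or fell by the size rule. The rule took 158 and 107 genes in the library labelled cKO over WT, 278 and 280 in Old over Young, and 28 and 36 in WT over Young.

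The comparison of Old with Young platelets addressed ageing between 3 and 24 months. Neutrophil markers were far higher in Old, and B cell, MHC class II and ribosomal protein genes were lower. S100a9 (chromosome 3, 90692632 to 90695721), an abundant calcium-binding protein of neutrophils, rose 40.1-fold (34.6 to 46.8; 6562 against 179 reads), and Mmp9, a gelatinase, rose 120-fold (60.7 to 279; 877 against 8 reads). Pax5, the transcription factor of the B cell lineage (chromosome 4, 44524757 to 44710487), was 3.95-fold lower (3.62 to 4.33; 602 against 2606 reads). Flna, the actin crosslinker filamin A, rose 2.91-fold (2.88 to 2.93), and F5, coagulation factor V, rose 2.60-fold (2.58 to 2.63). Of 6519 genes with at least 100 reads in the larger library 278 rose and 280 fell, and 83 and 25 passed at 4-fold.

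Lcn2, a siderophore-binding granule protein, had 434 reads in Old against 1 in Young, a ratio of 475 with a counting interval of 84.8 to 18812.9. Slfn4 (264 against 1 reads), Ngp (295 against 3) and Lilrb4a (218 against 2) had ratios of 289 (51.4 to 11460.5), 108 (36.5 to 525) and 119 (32.6 to 992). Cd14, Ltf, Dsp and Il1r2 had 0 reads in Young and were, against a floor of 3 reads, at least 68.6-fold, 68.3-fold, 39.8-fold and 39.4-fold higher in Old, with interval bounds of 55.3, 55.0, 31.8 and 31.5. Among the genes that fell, Fcer2a, a B cell surface receptor, was 18.0-fold lower (9.58 to 38.1), Calcrl, a peptide hormone receptor, 10.8-fold, Dennd4c 7.88-fold, Prps1, an enzyme of nucleotide synthesis, 12.2-fold, and Pold2, a DNA polymerase subunit, 10.8-fold. Lynx1 had 0 reads in Old and 105 in Young and was at least 32.0-fold lower against that floor (interval bound 25.5). Olfr56 was 69.6-fold lower, Tigd4 22.6-fold and Arfip1 10.1-fold. Hist1h2bh, 14.7-fold lower, belongs to a family of near-identical histone genes and is uncertain.

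The platelet gene list stood apart upward in Old against Young, but not against WT. Of 38 platelet receptor and granule genes 2 rose (F5 and the platelet tubulin Tubb1, 2.28-fold), 0 fell and 31 had a ratio above 1, with a median of 0.46 (percentile 99.95). Against WT the median was 0.29 and inside the random range (percentile 88.2). Thbs1 and Rgs18 had ratios of 1.27 and 0.818. Of 40 integrin and actin genes Flna and Itga2 (2.25-fold) rose, and the median was 0.36 (percentile 97.2). Tpm3, a tropomyosin, was 3.10-fold lower, but its near-identical copy Tpm3-rs7 was 11.6-fold higher, and the reads of both together had a ratio of 1.12 (1.09 to 1.14), so the fall of Tpm3 cannot be separated from how shared reads were assigned. Of 16 megakaryocyte transcription factors Runx1 fell 2.42-fold and 15 did neither (median -0.02). Of 17 secreted factors Ccl9 (9.85-fold), Il1b (7.50-fold), Ccl6 (4.72-fold) and Timp3 (2.79-fold) rose and Il16 fell (median 0.60, percentile 99.93). Of 29 reported HuR target mRNAs 5 rose and Cycs fell, with a median of 0.31 (percentile 97.6, the same with the 2 members at 0 reads set at their bound). Those that rose were Mmp9, Dusp1 (10.2-fold), Fos (10.1-fold), Il1b and Plaur (4.76-fold), of which Mmp9 is also on the neutrophil list. Cirbp, Hnrnpd and Khsrp fell 3.14-fold, 2.69-fold and 2.65-fold among 18 AU-rich element binding proteins (median -0.35, percentile 3.19), and 15 did neither.

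Ribosomal protein genes were lower as a group. Of 78 measured, 3 fell, 75 did neither and only 7 had a ratio above 1, giving a median of -0.64 (percentile 0). Rps7 fell 2.37-fold and Rps15a 2.20-fold. Rps3a1 fell 2.54-fold, and 1.88-fold (1.80 to 1.96) when its reads were added to those of the copy Rps3a2. Nuclear retained and structural RNAs had a median of 1.55 (percentile 100), and 4 of 6 rose: Malat1 15.4-fold (605 against 43 reads), Lars2, a protein-coding gene on that list, 9.21-fold, mt-Rnr1 3.34-fold and Neat1 2.56-fold. Stat2 (3.33-fold), Irf9 (2.76-fold) and Ddx58 (2.62-fold) fell among 40 interferon-stimulated genes, 37 did neither, and the median was -0.32 (percentile 5.51). Medians inside the random range were 0.37 for 21 senescence genes (Mmp9, Il1b, Plaur and Timp2 rose, Igfbp4 fell), 0.18 for 16 MHC class I genes (H2-K1 rose 2.32-fold, H2-Q6 fell 3.82-fold, both of a family with shared sequence), 0.07 for 12 mitochondrially encoded mRNAs (mt-Co3 rose 3.33-fold), -0.02 for 73 oxidative phosphorylation genes, -0.19 for 31 proteasome subunits, 0.37 for 19 glycolysis genes (Slc16a3, a lactate transporter, rose 8.88-fold), 0.01 for 21 immediate-early genes (Dusp1 and Fos rose), -0.09 for 24 cell cycle genes and -0.04 for 4 Y-linked genes.

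Leukocyte markers moved in different directions beside these groups. All 25 measured neutrophil markers had a ratio above 1 and 14 rose, among them S100a8 (35.1-fold), Mmp8 (50.6-fold), Cd177 (26.8-fold) and Cxcr2 (25.8-fold). Their median was 4.66, or 3.49 with the 6 members at 0 reads in 1 library set at their bound (percentile 100). Of 18 monocyte and macrophage markers Cd14, Fn1 (7.29-fold), Csf1r (5.38-fold) and Ccr2 (3.37-fold) rose (median 1.28), while the summed reads of the list had a ratio of 0.831. Of 22 B cell markers 12 fell, 0 rose and 1 had a ratio above 1 (median -1.67, percentile 0). Fcmr (3.94-fold lower) and Ly6d (3.76-fold lower) fell beside Fcer2a and Pax5. Of 16 MHC class II and dendritic cell markers 6 fell, led by H2-Oa (7.57-fold), H2-DMb2 (2.92-fold) and H2-DMa (2.87-fold), with a median of -1.02. Gzma (5.26-fold), Trac (3.82-fold), Lef1 (2.59-fold) and Tcf7 (2.43-fold) fell among 29 T and NK cell markers (median -0.87). Igha rose 10.6-fold while Iglc3 (5.52-fold), Mzb1 (5.30-fold) and 2 further plasma cell and immunoglobulin genes fell. The median of 15 was 0.34 (percentile 96.4), but it was -1.16 over the 7 with at least 200 reads over both libraries, outside the random range, and the summed reads had a ratio of 0.708. Hdc rose 8.04-fold and Il4 fell 6.83-fold among 4 basophil and mast cell markers (median 0.89), Flt1 rose 4.95-fold among 14 endothelial markers (median 0.70), and Hbb-bt fell 2.60-fold while Sptb rose 2.37-fold among 28 erythroid markers (median -0.11, percentile 2.98).

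Against WT, the other 3-month wild-type library (chosen after seeing the data), Old had 287 genes higher and 267 lower. Of the 278 and 280 genes past the rule against Young 191 and 132 also passed against WT, 0 in the opposite direction, and 3 of those that rose were not listed with WT. Both comparisons use the Old library, so agreement is partly built in. Opposite calls would need WT and Young to lie about 4-fold apart or more, so their absence adds little support. S100a9 (13.5-fold), Mmp9 (26.6-fold), Malat1 (13.5-fold), Flna (2.49-fold) and F5 (2.27-fold) remained higher and Pax5 (4.74-fold) and Rps7 (2.54-fold) lower, while Runx1, Fos, Il1b, Csf1r, Cirbp, Tcf7 and Lef1 did not pass. The neutrophil (2.92), secreted factor (0.48), structural RNA (0.87), B cell (-1.91), MHC class II (-1.31) and ribosomal (-0.62) medians stood apart again, and the senescence (0.59), glycolysis (0.48) and erythroid (0.66) medians stood apart upward though not against Young. The HuR target (0.26), monocyte (0.09), T and NK cell (-0.28), basophil (0.70) and endothelial (0.45) medians lay inside the random range. Scaling by the plain total shifted all Old over Young log2 ratios by -0.16, giving 225 genes higher and 425 lower, and the total without mitochondrial and haemoglobin genes gave 224 and 432. In the authors' deposited table, adjusted p was under 0.05 for 2004 genes (951 higher, 1053 lower), among them 546 of the 558 past the rule.

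WT and Young, both from 3-month-old wild-type males, show what 2 such libraries differ by without a change of genotype or age. They need not share strain, litter or day, and such differences cannot be told apart from the spread between pools. Of 6373 genes with at least 100 reads in the larger library 28 were higher and 36 lower in WT. Neutrophil markers S100a9 (2.97-fold) and S100a8 (2.94-fold) and the cytokine Il1b (3.91-fold) were higher in WT, and the red-cell genes Hba-a1 (2.58-fold), Hbb-bs (3.01-fold), Hbb-bt (3.27-fold), Alas2 (3.20-fold) and Tspo2 (5.0-fold) were lower. Dusp1 (3.77-fold), mt-Nd3 (3.44-fold), Igfbp5 (3.41-fold), Traf5 (3.13-fold) and Lst1 (3.03-fold) were also higher, and Gphn (6.01-fold), Rinl (3.20-fold) and Fam220a (3.13-fold) lower. Hist1h4n and Rps27rt (higher) and Hist1h2br and Hist1h2bh (lower) share reads with copies and are uncertain. The 2 tables were scaled separately by the authors, so these ratios rest on recovered reads scaled together anew. The plain total shifted this comparison by -0.11 on the log2 scale and gave 16 genes higher and 51 lower, and the total without mitochondrial and haemoglobin genes gave 15 and 52.

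Many of the marker lists stood apart between these 2 wild-type libraries too. The medians were 1.32 for neutrophil markers (2 of 16 higher), 0.75 for monocyte and macrophage markers (Fn1 2.80-fold higher), 0.54 for plasma cell and immunoglobulin genes (Igha 2.87-fold higher), 0.29 for B cell markers (0 of 22 passed), 0.26 for MHC class II and dendritic cell markers (Itgax 2.95-fold higher), -0.64 for T and NK cell markers (Bcl11b 2.87-fold lower) and -0.61 for erythroid markers (9 of 29 lower, 0 higher). Mitochondrially encoded mRNAs (0.44) and immediate-early and heat shock genes (0.29) stood apart upward, and AU-rich element binding proteins (-0.28; Cirbp 2.84-fold lower) and megakaryocyte transcription factors (-0.20) downward, both with a ratio of summed reads of 1.02. The other 16 lists lay inside the random range, with medians of 0.14 for platelet genes, 0.11 for integrin and actin genes, 0.26 for secreted factors, 0.13 for HuR targets, -0.08 for senescence genes, 0.13 for interferon-stimulated genes (Isg15 3.19-fold lower), 0.01 for MHC class I (summed reads had a ratio of 1.56) and ribosomal protein genes, -0.04 for oxidative phosphorylation, 0.05 for the proteasome, -0.07 for glycolysis, -0.05 for cell cycle genes, 0.03 for basophil and mast cell markers (Hdc 2.97-fold higher), 0.32 for endothelial markers, 0.45 for nuclear retained and structural RNAs and 0.13 for Y-linked genes. With the spread of WT over Young at the same expression as a yardstick, 15.0% of genes in the library labelled cKO over WT lay outside its central 95% (473 above, 467 below, Elavl1 above), and 20.5% in Old over Young (705 above, 630 below, Elavl1 within). With a minimum of 500 reads these were 22.57% and 23.02%, so the gap between the 2 depends on the minimum.

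**Figure D3:**
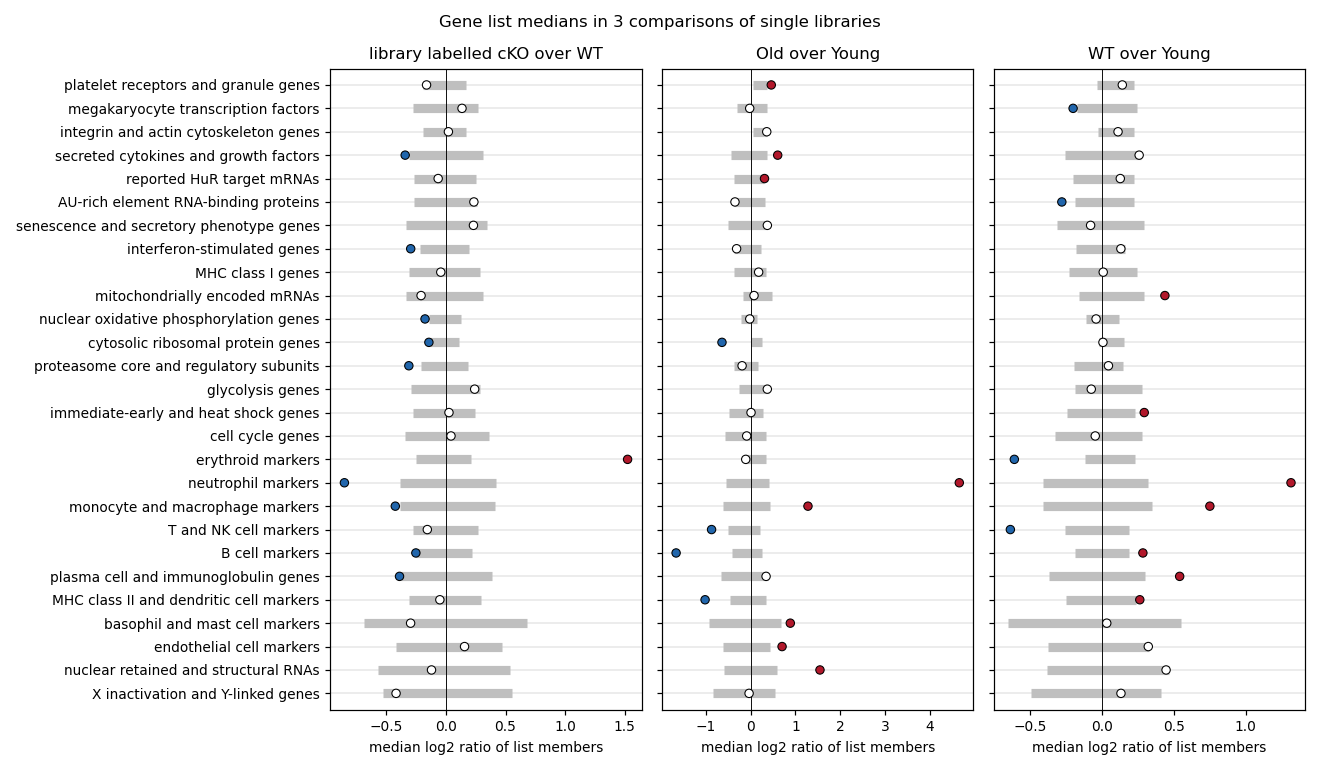
Median log2 ratio (x axis) of the members of 27 gene lists (y axis) in 3 comparisons of single libraries; grey bars are the central 95% of 10000 random lists matched on expression, filled circles lie outside it and open circles inside. Erythroid markers were at 1.52 in the library labelled cKO over WT and -0.61 in WT over Young. Neutrophil markers were at 4.66 in Old over Young (25 measured members) and 1.32 in WT over Young (16 measured members).

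The last comparison asked whether the library labelled cKO differed from WT in the same genes as Old from Young. Col18a1 (7.59-fold and 5.44-fold), Prx, a periaxin scaffold gene (5.14-fold and 4.98-fold), Pnck (3.61-fold and 4.77-fold) and Kifc3, a kinesin motor (4.21-fold and 3.54-fold), were higher in both, and the growth factor gene Nrg4 was lower in both (ratios 0.240 and 0.285). Hist1h3c was also higher in both and is uncertain, as are other histone genes. Ociad2 (0.159 and 3.39), Clca3a1 (0.333 and 3.03), Pkd1l3 (0.357 and 4.68) and Slc27a2, a fatty acid transporter (2.81 and 0.300), went in opposite directions, as did BC016579 and Hist1h4m. Over 5986 genes with at least 100 reads in the larger library of each comparison, 15 went past the rule in the same direction and 12 in opposite directions, where independent lists would share 7.54 and 7.92. Both higher were 11 (3.45 if independent), both lower 4 (4.09), higher in the library labelled cKO and lower in Old 5 (5.21), and the reverse 7 (2.71). In this pairing the excess lay in genes higher in Old, whichever way they went in the library labelled cKO. The log2 ratios had a Pearson correlation of 0.014 and a Spearman correlation of 0.003 across genes, which are not independent replicates. The 2 comparisons share no library. The crossed pairing set the library labelled cKO over Young against Old over WT. There both higher were 10 (2.92 if independent), both lower 6 (1.78), higher in the library labelled cKO and lower in Old 5 (4.05), and the reverse 5 (1.29). Genes lower in both were thus in excess too, so where the excess lay depends on the pairing.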

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

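The other 3-month wild-type library as reference was chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each group holds 1 library, so the groups share fewer than 2 replicate numbers. Median-of-ratios scaling, protein-coding genes only and thinning to the smallest library kept every count of genes that rose or fell within 1.5 times the reported one. Counts are given as genes higher and lower for the library labelled cKO over WT, then Old over Young, then WT over Young. A minimum of 20 reads gave 307 and 264, then 602 and 592, then 134 and 159, and no minimum gave 422 and 419, 888 and 850, and 239 and 239. A minimum of 500 reads gave 80 and 59, 101 and 75, and 6 and 14. The point ratio without an interval gave 290 and 230, 439 and 647, and 93 and 134, and an interval bound of 4-fold gave 20 and 7, 83 and 25, and 0 and 4. These follow from testing more or fewer genes or from a looser or stricter bound. The authors' deposited fold changes at 2-fold gave 289 and 228, and 439 and 644. They give no value for WT over Young, and the tables hold no FPKM. Plain totals gave 425 genes lower in Old and 16 higher in WT over Young, and totals without mitochondrial and haemoglobin genes 432 and 15, since both move every ratio downward. The latter shifted the library labelled cKO over Young by -0.10 on the log2 scale. With Young as reference 51 genes were lower in the library labelled cKO. Genes past the rule in both comparisons numbered 35 in the same and 37 in opposite directions at a minimum of 20 reads, 2 and 7 at 500 reads, and 2 and 0 at a 4-fold bound. Crossed pairing gave 16 in the same and 10 in opposite directions, where independent lists would share 4.70 and 5.33. The correlation across genes was 0.074 with crossed pairing and -0.048 at a minimum of 500 reads. At that minimum 22.6% of genes in the library labelled cKO over WT and 23.02% in Old over Young lay outside the yardstick. Elavl1 was 2.62 times Young in the library labelled cKO, and 0.603 times WT in Old. The cause was not tested for these last values.

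Of 621 planned list results 583 kept their side of the random range, 17 moved inside it, 20 moved outside it with the same sign and 1 moved outside it with the other sign. The 1 was the plasma cell and immunoglobulin list in Old over Young, at -1.16 with a minimum of 200 reads, which leaves 7 members. All lists among the 583 that stood apart kept their direction, but 33 medians inside the range changed sign there: 8 with plain totals, 9 with totals without mitochondrial and haemoglobin genes, 2 with median of ratios, 5 with a minimum of 200 reads, 4 with no minimum and 5 with the mean. The 3 other scalings moved none of their 81 results each across the random range. This was fixed in advance, since a scaling shifts every log2 ratio of a comparison, random lists included, by the same amount. Those results are counted among the 583 and add no support. The authors' fold changes moved none of 54, but they are nearly the same values. Their median absolute difference was 0.0003 for the library labelled cKO over WT and 0.0004 for Old over Young on the log2 scale. With the other wild-type library as reference 35 of 54 kept their side of the range (13 of them changed sign inside it), 7 moved inside, 6 moved outside with the same sign and 6 that stood apart with 1 or the other reference changed sign: in the library labelled cKO secreted factors (0.11), neutrophil (0.21), monocyte (0.67), B cell (0.17) and plasma cell genes (0.055), and in Old erythroid markers (0.66). In all of these lists but secreted factors WT and Young themselves stood apart. Depth limits what can be said of genes under 100 reads, where a 2-fold ratio often lies within counting error.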

Other observations

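All tests in this part were chosen after values of single genes had been seen, as were the genes named here that are on no gene list chosen before any value was seen.

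Further single genes differed in the library labelled cKO. They were picked one by one and stand for no gene group. Both subunits of soluble guanylate cyclase, the nitric oxide receptor, were lower than in WT: Gucy1a1 by 2.70-fold (2.25 to 3.25) and Gucy1b1 by 2.08-fold (2.00 to 2.15), and the phosphodiesterase Pde3a was 3.46-fold lower (3.12 to 3.83). Against Young Pde3a was 2.62-fold lower and passed the rule again, while Gucy1a1 (2.08-fold) and Gucy1b1 (1.69-fold) did not pass. Serpinb2, an inhibitor of plasminogen activators, was 3.96-fold lower than in WT and 3.43-fold lower than in Young. Higher than in both wild-type libraries were Cnn1 5.65-fold over WT and 9.63-fold over Young, Ppp1r14a 5.19-fold and 5.17-fold, Kcnmb1 3.32-fold and 3.33-fold, Fhl3 2.20-fold and 2.74-fold, and Cavin3 4.26-fold and 4.75-fold. Of 14652 genes listed in both tables, 65 lay past the rule from each of the 3 other libraries in the library labelled cKO (45 higher, 20 lower), 237 in Old (157 higher, 80 lower), 8 in WT and 7 in Young.

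Some of the genes that stood apart in Old lie next to each other. Arfip1 and Tigd4 on chromosome 3 were 10.1-fold and 22.6-fold lower than in Young, and Olfr56 on chromosome 11 was 69.6-fold lower beside 9930111J21Rik2, which fell too and whose annotated span overlaps it. In all, the genes that rose in the library labelled cKO over WT formed 14 pairs within 200000 bases of each other, where 1000 random draws gave a median of 5 and at most 14, while those that fell formed 3 against a median of 2 and a maximum of 8. In Old over Young, 29 pairs rose against a median of 17 and a maximum of 32, and 22 fell against 17 and 29. In WT over Young 2 pairs were higher, against 0 and 2, and 2 were lower, against 0 and 3. Some pairs were of the same gene family, such as Hbb-bt with Hbb-bs and S100a8 with S100a9. The random draws took no account of families or shared reads, so no regional effect can be read from these counts.

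Elavl1 was 1.66 times the WT level in the library labelled cKO. A swap of the 2 labels would make the library labelled WT the one that stands apart, but it did so in 8 genes against 65 for the library labelled cKO. This argues against a swap, on the assumption that loss of HuR changes more genes than the choice of wild-type mice does. Reads from exons outside the deleted part could keep the gene-level count from falling whatever the protein does. By themselves they do not account for a ratio above 1, and no exon-level value is at hand. A change of Elavl1 transcription or stability with the genotype, or a difference between pools, stays open and untested.

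Erythroid genes were higher in the library labelled cKO than in WT. More red-cell RNA of a fixed composition would move haemoglobin and the other red-cell genes alike against Young too, but haemoglobin was at 0.760 of Young (0.756 to 0.764) while the median log2 ratio of the 19 other erythroid genes with at least 100 reads in the larger library was 0.55, with 17 of 19 above a ratio of 1 and quartiles of 0.28 and 1.48. That argues against 1 composition shared by the library labelled cKO and Young. It does not decide the difference from WT, over which haemoglobin was higher too, at a ratio of 1.77 (1.76 to 1.78). A different composition, such as younger red cells, stays open. The genotype may also contribute, since the list stood apart upward against both wild-type libraries (1.52 and 0.55), but WT lay below Young in the same list (-0.61), so genotype and a difference between pools cannot be told apart with 1 library each.

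Neutrophil genes were higher in Old than in Young. A lower share of platelets with more leukocytes of every kind would raise B cell genes as well, but their median log2 ratio was -1.67, which argues against it. RNA of neutrophils in the preparation stays open, since the 17 of 20 measured neutrophil genes that were 2-fold or more higher in Old than in WT as well come from a comparison that shares the Old library; among them were the abundant S100a8 (4164 reads in Old against 350 in WT, 155 in the library labelled cKO and 130 in Young) and S100a9 (6562 against 487, 231 and 179). The labels name no gate that would remove these cells, and 1 of the list's genes, Mmp9, is also on the HuR target and senescence lists. An effect of age on the blood or on platelets themselves stays open and untested, since age and the pool of mice are the same split here.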
